A study of Mus musculus with 6 samples.

How the data were processed

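RNA from 6 samples of differentiated mouse cortical neural progenitor cells was sequenced, 3 expressing GFP and 3 expressing G392E neuroserpin. The deposited table holds raw gene counts, whole numbers per Ensembl gene and library that are not normalised, as the values themselves and per the labels show. The submitters' processing notes name TopHat2 2.0.12, HTSeq 0.6.1, R 3.2.2, DESeq2 1.4.5 and the mouse genome build GRCm38, without saying what each was used for. The annotation release, the strand setting and any filter are not given in the sources used here. The strand setting bears on antisense pairs, and multi-mapped reads bear on near-identical genes. Some such genes are named as uncertain in the text, but not all. Genes given without such a remark can also overlap another gene, as Cryab does Hspb2, Ctsz does Nelfcd and Ryr3 does Aven.

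Groups and replicate numbers were taken from the labels, and each column of the table was matched to a sample by its name. The table holds 39179 genes, of which 15991 had no counts in any library and 37693 were paired with a symbol and position by GENCODE release M21 (GRCm38). Replicates were compared before use: over genes with at least 10 counts in a pair, the chi-square statistic per degree of freedom was 8.02 to 56.4, far above sampling noise, so no pair was a duplicate. The libraries held 15507487 to 24835835 counts, and the biological coefficient of variation was 0.159.

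Gene tests were made with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes with low counts were removed with filterByExpr, which left 13775 genes holding 99.9% of all counts. Libraries were scaled with TMM factors, and a quasi-likelihood F test compared the groups with no covariate. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 fold changes are of G392E-NS over GFP, and standard errors were taken from the fold change and its F statistic. CPM values are scaled by the TMM factors and given as mean ± SD. Where a group had no counts, a fold is given as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with a 95% exact binomial interval. Intervals and floors cover counting error only.

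The comparison, the tests, the gene lists, the rule for named genes and all alternatives but 2 were chosen before the data were examined. The 31 lists cover oxidative stress (NRF2 targets, antioxidant enzymes, glutathione transferases), protein quality control (unfolded protein response, amino acid response, ER-associated degradation, proteasome, autophagy and lysosome, heat shock), inflammation and interferon, calcium handling, metabolism, p53 targets, ribosomal proteins, immediate early genes, matrix, serpins, the cell cycle and markers of cell types. Lists with at least 5 genes tested, 30 of 31, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, with p adjusted over the lists. Fry tests whether a list's genes move on balance 1 way, and its mixed test whether they change in either direction. The text names Serpini1, 9 genes fixed for the question (Hmox1, Cat, Sod1, Hspa5, Ddit3, Nes, Tubb3, Map2 and Gfap), the 8 genes with the largest fold change in each direction among called genes whose groups do not overlap and whose mean is at least 1 CPM, and up to 4 called members of each list, or the nearest member where none passed. Not every gene that the rule picks is described in the text. Genes outside this rule are named as chosen after their values were seen.

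The alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, counts thinned to the smallest library, a 2-fold minimum, and leaving out each library in turn. Leaving out genes on X and Y, and removing trends on gene length and GC content, were chosen after seeing the data. Length and GC content were known for 99.0% of the genes tested.

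The tests were tried on counts simulated from the means, depths and dispersions of these libraries, with 200 expressed genes drawn at random and changed up or down, 50 at each fold. For G392E-NS against GFP, edgeR over 13575 simulated genes recovered 30% of genes changed 1.5-fold, 72% of those changed 2-fold, 90% at 3-fold and 96% at 4-fold, and 6 of its 150 calls were false. DESeq2 made 28 false calls of 182 and limma-voom 7 of 151. In simulated lists over 13589 genes, camera at the preset correlation called the 1 list shifted by 0.5 and none of the other 29, while camera with an estimated correlation did not call it. The simulated genes were drawn independently, whereas real lists had estimated correlations such as 0.43 for NRF2 targets and 0.85 for cholesterol synthesis. The simulation therefore does not show how often camera at the preset correlation calls unshifted lists of correlated genes.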

Results

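RNA was sequenced from mouse neural progenitor cells, the dividing precursors of neurons and glia, that had been taken from the cerebral cortex of CD1 embryos at stage E13.5 and differentiated in culture. The cells stably expressed either green fluorescent protein (GFP) or the G392E variant of neuroserpin (G392E-NS). Neuroserpin is a serine protease inhibitor secreted by neurons. Its G392E variant polymerises inside the endoplasmic reticulum (ER) and causes the dementia FENIB, familial encephalopathy with neuroserpin inclusion bodies. The 6 libraries formed 2 groups of 3. Total counts were 16958952, 19543176 and 22936447 for GFP replicates 1 to 3, and 24143966, 24835835 and 15507487 for G392E-NS replicates 1 to 3. Between 18573 and 19582 genes had at least 1 count in a library. The comparison asks which genes differ between cells carrying the neuroserpin variant and GFP cells, and whether oxidative stress genes are among them. Cells expressing wild-type neuroserpin were not analysed here, so the variant is compared with GFP alone. The first principal component of log2 CPM (counts divided by library size) held 61.7% of the variance and separated the groups, with scores of −42.1 to −25.1 in GFP and 24.8 to 47.5 in G392E-NS libraries. Nothing in the labels says whether the replicates came from separate cultures or from 1 culture per group. The p-values therefore measure the spread between these samples, which may be technical, and may not cover the spread between separately derived cultures.

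Serpini1, the mouse neuroserpin gene (ENSMUSG00000027834, GRCm38 chromosome 3, 75557547 to 75643495), had 4.69 ± 0.483 CPM in GFP and 5.72 ± 0.924 CPM in G392E-NS libraries (mean ± SD, n = 3 each). Its log2 fold change of 0.29 (SE 0.19) did not pass the test, with an adjusted p of 0.419. The counts are of mouse genes, and the labels do not say from which species the introduced neuroserpin came. It therefore cannot be told whether this value holds reads of the introduced gene, and expression of the construct could not be checked. The groups differed in sex-linked transcripts. Xist, the RNA that silences one X chromosome in female cells (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), rose from 1.51 ± 0.0831 CPM in GFP to 1494 ± 345 CPM in G392E-NS libraries, a log2 fold change of 9.95 (SE 0.26, adjusted p = 2.47e-06). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, chosen after their values were seen, were detected in all 6 libraries and fell by 0.93, 0.92, 0.97 and 1.11 on the log2 scale, with adjusted p of 0.000844 to 0.00348. Reads of Xist and of its antisense partner Tsix cannot be told apart, since the sources used here do not say whether counting used strand.

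**Figure D1:**
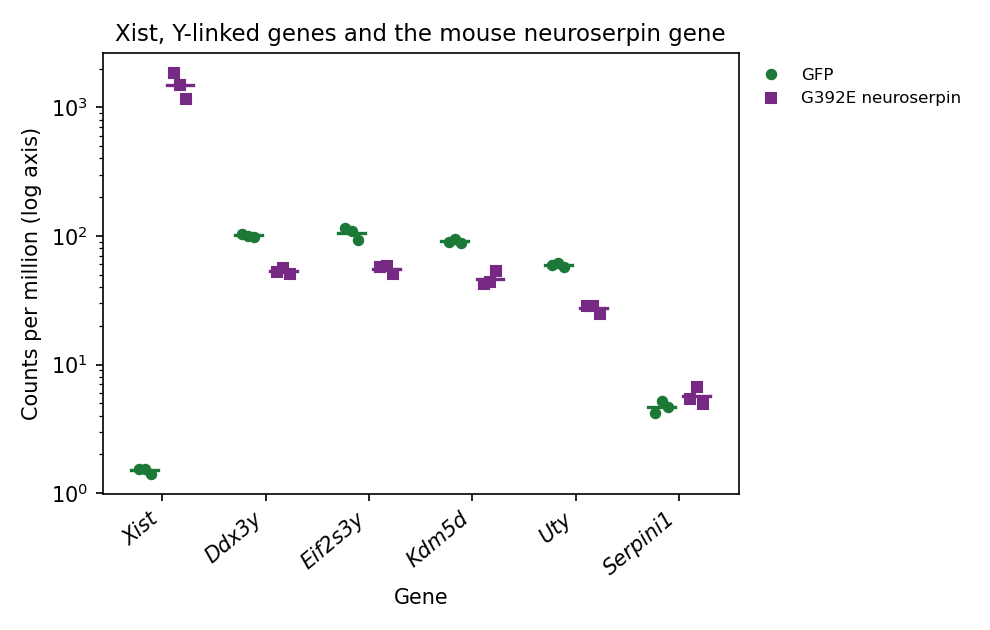
CPM (log axis) of Xist, 4 Y-linked genes and Serpini1 in each library, with GFP as green circles, G392E neuroserpin as purple squares and group means as horizontal lines (n = 3 each). Xist lies between 1.41 and 1.56 in GFP and between 1156 and 1846 in G392E neuroserpin libraries, while the Y-linked genes are present in all libraries and lower in the second group.

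Of 13775 genes tested, 660 were higher and 187 lower in G392E-NS libraries at an adjusted p under 0.05 (edgeR quasi-likelihood test), so that 77.9% of the 847 calls were higher. At least a 2-fold difference was found for 452 of the higher and 86 of the lower genes. Among the genes with the largest increases were Ramp1, a co-receptor subunit of the calcitonin gene-related peptide receptor, Rgl3, Pdk4, a kinase that restrains pyruvate oxidation, and Cavin1, a coat protein of caveolae. Cavin1 (ENSMUSG00000004044, chromosome 11, 100956733 to 100970887) rose 112-fold, from 0.193 ± 0.0559 to 22.7 ± 9.49 CPM (log2 fold change 6.81, SE 0.43, adjusted p = 0.00018). Ramp1 (ENSMUSG00000034353, chromosome 1, 91179822 to 91225196) had 1 count in the GFP libraries together and 734 in the G392E-NS libraries, a depth-scaled ratio of 707 (95% exact counting interval 127 to 27972). The same ratio was 275 for Rgl3 (75.8 to 2277), 217 for Pdk4 (38.5 to 8601) and 146 for Xlr3b (49.6 to 710). Xlr3a and Twist1, a mesenchymal transcription factor, had no counts in GFP libraries and were at least 45.9-fold and 41.4-fold higher against a floor of 3 counts over the group. Xlr3a and Xlr3b are near-identical copies, so the split of reads between them is uncertain.

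Among the lower genes with the largest changes, the transcription factor gene Pax9 (ENSMUSG00000001497, chromosome 12, 56691767 to 56712822) fell 14.5-fold, from 4.41 ± 0.582 to 0.289 ± 0.0895 CPM (log2 fold change −3.86, SE 0.29, adjusted p = 0.000438). Isl2, which specifies motor neurons, fell 10.5-fold and Neurod1, which drives neuronal differentiation, fell 6.17-fold. En2, a transcription factor of the midbrain and hindbrain (ENSMUSG00000039095, chromosome 5, 28165694 to 28172166), fell 10.4-fold from 16.5 ± 1.72 to 1.63 ± 0.469 CPM, and its chromosomal neighbour Cnpy1 fell 8.73-fold. The remaining genes of this kind were the collagen gene Col5a2 (9.49-fold lower), Vwa5b1 (9.45-fold) and Cd93 (8.80-fold), with adjusted p of 0.0101, 0.00633 and 0.0189. Pax9 overlaps Slc25a21 and Neurod1 overlaps Cerkl, so their counts may hold reads of those genes. Over all genes tested, 28.6% had no overlap between the groups, against 10% by chance for 3 against 3 if the samples are independent, which is not known here.

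The number of calls moved when a library was left out, which also leaves fewer samples for each test. The counts of higher and lower genes were 196 and 46 without GFP replicate 1, 207 and 51 without GFP replicate 2, and 428 and 85 without G392E-NS replicate 2. Without GFP replicate 3 the higher genes numbered 382, and without G392E-NS replicate 1 there were 981, which made up 71.4% of the calls, as the lower genes more than doubled. Of the 16 genes named above for their fold change, Cd93 lost its call without GFP replicate 1, GFP replicate 2 or G392E-NS replicate 3 (adjusted p = 0.0758, 0.056 and 0.0673). With trends on gene length and GC content removed, an alternative chosen after seeing the data, 662 genes were higher and 442 lower, a share of 60.0% higher against 77.9%.

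Genes of oxidative stress defence included several that rose in G392E-NS libraries, mostly glutathione transferases. The ferritin heavy chain gene Fth1, which stores iron (ENSMUSG00000024661, chromosome 19, 9980598 to 9985098), rose 3.71-fold from 304 ± 52.8 to 1128 ± 494 CPM (log2 fold change 1.89, SE 0.32, adjusted p = 0.0149). It was the 1 of 24 NRF2 target genes that passed the test (2 adjusted over the list alone), and 21 of the 24 had a fold change above 0. Of 15 glutathione transferases, enzymes that conjugate glutathione to reactive compounds, Gstt1, Gstt3, Gstm1 and Gstm5 rose (6 higher and 1 lower adjusted over the list alone). Gstt1 (ENSMUSG00000001663, chromosome 10, 75783813 to 75798584) rose 13.8-fold from 2.29 ± 0.552 to 31.6 ± 18.4 CPM (adjusted p = 0.00279), Gstt3 5.37-fold and Gstm1 3.14-fold, and Gstm5 rose by 0.58 on the log2 scale. Glutathione transferases of a family are similar in sequence, so reads may be split between them. Of 30 genes on the antioxidant enzyme list, 1 rose, and 1 adjusted over the list alone. It was Mt3 (3.59-fold, adjusted p = 0.0311), which encodes a metallothionein and not an enzyme. The share called on this list and among NRF2 targets did not exceed the 6.15% called over all genes tested. Among glutathione transferases, with 4 of 15 called, it did. The genes fixed for this question did not pass the test: Hmox1, which degrades haem, had a log2 fold change of 0.70 (SE 0.31, adjusted p = 0.232), the catalase gene Cat 0.36 (SE 0.16, adjusted p = 0.239) and the superoxide dismutase gene Sod1 0.47 (SE 0.18, adjusted p = 0.176).

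As whole lists, glutathione transferases (median log2 fold change 0.57) and NRF2 targets (0.46) lay above other genes by camera, with adjusted p of 0.000622 and 0.00824. Antioxidant enzymes (median 0.14) did not, at 0.0735, but did without GFP replicate 3 (0.0419), without G392E-NS replicate 1 (0.00198) and with no low-count filter (0.0032). With an estimated correlation neither call held, with adjusted p = 0.810 with an estimated correlation for glutathione transferases and adjusted p = 0.854 with an estimated correlation for NRF2 targets. No list of the 30 tested passed with an estimated correlation. By camera at the preset correlation, other splits of the 6 libraries gave 6 to 16 lists, against 9 for the real groups. Astrocyte markers had a median log2 fold change of 1.24 in the same libraries. Without G392E-NS replicate 2 the medians of glutathione transferases and NRF2 targets were 0.21 and 0.24, and the NRF2 list lost its call (adjusted p = 0.0805). Without GFP replicate 1 or GFP replicate 2, Fth1, Mt3, Gstt3, Gstm1 and Gstm5 lost their calls, with adjusted p of 0.0796 to 0.137 and 0.0558 to 0.132. The calls of Gstt3 and Gstm5 were also lost without GFP replicate 3 (0.067 and 0.0703), those of Mt3 and Gstm5 without G392E-NS replicate 2 (0.0639 and 0.0731), and those of Mt3, Gstm1 and Gstm5 without G392E-NS replicate 3 (0.0502 to 0.0724). Hmox1 passed without G392E-NS replicate 1 (0.0339). The NRF2 targets called numbered 0 without GFP replicate 1 or 2 and 6 without G392E-NS replicate 1, with 3 by DESeq2 and 6 with no low-count filter. Antioxidant enzymes called numbered 0 without GFP replicate 1, GFP replicate 2 or G392E-NS replicate 3 and 5 without G392E-NS replicate 1, with 3 by DESeq2 and 7 with no low-count filter. Glutathione transferases called numbered 1 without GFP replicate 1 or 2, and 2 without GFP replicate 3 or G392E-NS replicate 3.

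**Figure D2:**
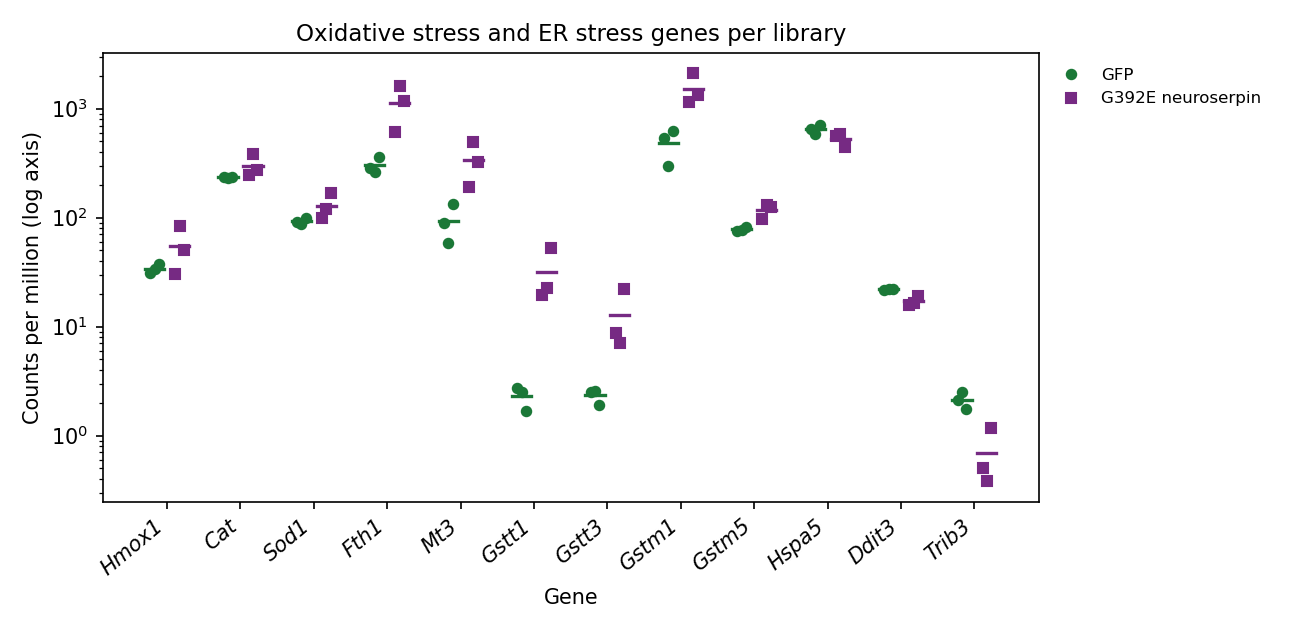
CPM (log axis) in each library for genes of oxidative stress defence and of ER stress, with GFP as green circles, G392E neuroserpin as purple squares and group means as horizontal lines (n = 3 each). Fth1, Mt3, Gstt1, Gstt3, Gstm1 and Gstm5 lie higher in all 3 G392E neuroserpin libraries than in any GFP library, and Trib3 lies lower. Cat also lies higher and Hspa5 and Ddit3 lower in this way, though these genes did not pass the test.

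Genes of the unfolded protein response, the programme that answers misfolded protein in the ER, lay slightly lower. Of 29 tested, 1 fell and none rose (0 adjusted over the list alone): Trib3, a pseudokinase induced by ER stress (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032), fell 3.26-fold from 2.13 ± 0.378 to 0.685 ± 0.428 CPM (log2 fold change −1.71, SE 0.41, adjusted p = 0.0486). The ER chaperone gene Hspa5 had a log2 fold change of −0.30 (SE 0.13, adjusted p = 0.238) and Ddit3, which encodes CHOP, of −0.35 (SE 0.11, adjusted p = 0.118). Ddit3 overlaps Mars, so its count may hold reads of that gene. The list had a median log2 fold change of −0.14 and camera placed it below other genes (adjusted p = 0.0117; adjusted p = 0.810 with an estimated correlation). That median was −0.09 without G392E-NS replicate 3. Of 24 amino acid response genes driven by ATF4, 2 rose and 3 fell (4 and 6 adjusted over the list alone). The folate enzyme gene Mthfd2, the stress-induced Nupr1 and Trib3 fell, by 0.81, 1.71 and 1.71 on the log2 scale, and the glycine transporter gene Slc6a9 and the mTOR inhibitor gene Ddit4 rose by 0.87 and 0.39. That list did not shift (median 0.04, mean −0.07, camera downward, adjusted p = 0.558), so that its median differed in sign from its mean and its test.

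Other lists of protein quality control held few calls with all 6 libraries. Of 24 genes of ER-associated degradation and 31 proteasome subunits, none passed in either direction over all genes or adjusted over the list alone (edgeR quasi-likelihood test). Their medians were 0.02 and −0.02 and camera's adjusted p were 0.975 and 0.499. The smallest adjusted p were 0.0534 for Derl3 and 0.22 for Psmc2. Of 33 autophagy and lysosome genes, 1 rose (1 adjusted over the list alone), the cathepsin gene Ctsz, by 3.01 on the log2 scale (SE 0.35, adjusted p = 0.00318). Its list had a median of 0.09 and an adjusted p of 0.326, which became 0.0169 without G392E-NS replicate 1, where 8 members were called higher. Of 18 heat shock chaperones, Cryab, Bag3 and Hspa4l rose by 1.80, 1.02 and 0.45 (3 adjusted over the list alone). This list had a median of −0.13, a mean of 0.07 and a downward camera direction (adjusted p = 0.631).

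Most calls among these stress genes were lost with a library left out, with no change of direction. Without GFP replicates 1, 2 and 3 in turn, Mthfd2 had log2 fold changes of −0.90, −0.80 and −0.73, Trib3 of −1.70, −1.57 and −1.84, and Cryab of 1.77, 1.74 and 1.91. Without G392E-NS replicate 2, Bag3 had 0.70, Cryab 1.32, Trib3 −1.40 and Nupr1 −2.21. Trib3, Mthfd2, Nupr1, Slc6a9, Ddit4, Cryab, Bag3 and Hspa4l each lost their call without GFP replicate 1 (adjusted p = 0.0551 to 0.193), without GFP replicate 2 (0.0961 to 0.196) and without GFP replicate 3 (0.0533 to 0.107). Some were also lost without G392E-NS replicate 1 (Trib3 and Hspa4l, 0.0896 and 0.0611), G392E-NS replicate 2 (Trib3, Ddit4, Bag3 and Hspa4l, 0.067 to 0.128) and G392E-NS replicate 3 (Nupr1, Slc6a9, Ddit4, Cryab and Bag3, 0.0571 to 0.0836). Ctsz kept its call in each of these. Without G392E-NS replicate 1, 4 amino acid response genes were higher, and without G392E-NS replicate 3, 2 unfolded protein response genes were lower. Limma-voom did not call Ddit4, Cryab, Bag3 or Hspa4l (0.0527 to 0.0711). Over 17 alternative settings, left-out libraries included, Hspa4l lost its call in 11, Ddit4 and Bag3 in 10 each and Trib3 in 7. Cryab lost its call in 6 of these settings, Nupr1 and Slc6a9 in 5 each and Mthfd2 in 4.

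Interferon response genes included 3 of 19 tested that rose (7 higher and 1 lower adjusted over the list alone). The viral RNA sensor gene Ifih1 rose by 3.16 on the log2 scale (SE 0.48, adjusted p = 0.00985), Ifi35 by 2.82 (SE 0.44, adjusted p = 0.0109) and the antigen presentation gene H2-D1 by 0.77 (SE 0.16, adjusted p = 0.0341). Ifih1 and Ifi35 were low, at 0.929 ± 0.202 and 0.738 ± 0.139 CPM in G392E-NS libraries. H2-D1 belongs to a family of similar genes whose reads may be split. The list had a median of 0.37 and camera placed it above other genes (adjusted p = 0.0274; adjusted p = 0.854 with an estimated correlation), a call lost without G392E-NS replicate 2 (0.162) and with at least 1 CPM required in 3 libraries (0.255). Its higher members numbered 0 without GFP replicate 1, 1 without GFP replicate 2 and 7 without G392E-NS replicate 1, with 7 by DESeq2 and 8 with no low-count filter. Its median was 0.66 without GFP replicate 3, 0.59 without G392E-NS replicate 1, 0.77 by DESeq2 and 0.78 with no low-count filter. Of 11 NF-kappaB and inflammatory genes, 1 rose (1 adjusted over the list alone), the NF-kappaB inhibitor gene Nfkbia, by 0.45 (SE 0.11, adjusted p = 0.0494). Nfkbia lost this call in 15 of 17 alternative settings, among them RLE and upper-quartile scaling (adjusted p = 0.0512 in each). The NF-kappaB and inflammatory list had a median of 0.47 and an adjusted p of 0.11. Of 15 immediate early genes, which respond to signalling within minutes, Jun and Fos rose by 0.62 and 1.37 (5 adjusted over the list alone, list median 0.13, adjusted p = 0.181, and 0.019 with no low-count filter).

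Of 22 genes that handle calcium at the ER and plasma membrane, 3 rose and 1 fell (6 and 6 adjusted over the list alone). The plasma membrane calcium pump gene Atp2b4 rose by 1.56 (SE 0.17, adjusted p = 0.00217), the ER calcium sensor gene Stim1 by 0.58 and the sodium-calcium exchanger gene Slc8a2 by 1.13, while the ryanodine receptor gene Ryr3, a calcium release channel, fell by 0.73 (SE 0.09, adjusted p = 0.00382). The list did not shift (median −0.11, mean 0.05, camera downward, adjusted p = 0.967). Among the interferon, inflammatory, early response and calcium genes, Nfkbia, Ifih1, Ifi35, H2-D1, Stim1, Slc8a2, Jun and Fos lost their calls without GFP replicate 1 (0.0588 to 0.137), and all of these but Ifi35 without GFP replicate 2 (0.0533 to 0.232). Nfkbia, H2-D1 and Fos also lost theirs without GFP replicate 3 (0.0697 to 0.114) and without G392E-NS replicate 2 (0.0764 to 0.101). Nfkbia, Slc8a2 and Jun did so without G392E-NS replicate 1 (0.0529 to 0.0596), and these with H2-D1 and Fos without G392E-NS replicate 3 (0.0701 to 0.0926).

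Genes of energy metabolism rose in part. Of 45 nuclear genes of oxidative phosphorylation, 8 rose and none fell (12 adjusted over the list alone). The complex III subunit gene Uqcrfs1 rose 1.52-fold (SE of the log2 fold change 0.11, adjusted p = 0.0194), Cox5a 3.63-fold, Ndufs1 1.42-fold and Cox6a1 1.65-fold, and 40 of the 45 had a fold change above 0. The list had a median of 0.24 (camera adjusted p = 0.000622; adjusted p = 0.854 with an estimated correlation). None of 12 mitochondrially encoded genes passed, over all genes or adjusted over the list alone (median 0.17, adjusted p = 0.631), though the list did without G392E-NS replicate 3 (median 0.39, adjusted p = 0.00775), and its median turned to −0.11 without G392E-NS replicate 2. The count of 8 oxidative phosphorylation genes fell to 0 without GFP replicate 1, 2 or 3 and to 4 without G392E-NS replicate 2 or 3, and was 2 by limma-voom and 3 with library totals alone. The list median was 0.07 without G392E-NS replicate 3 and 0.09 with length and GC trends removed. Of 24 glycolysis and hypoxia genes, 7 rose and none fell (9 adjusted over the list alone). The neuronal glucose transporter gene Slc2a3 (ENSMUSG00000003153, chromosome 6, 122727809 to 122801640) rose 2.55-fold from 7.08 ± 0.218 to 18.0 ± 2.84 CPM (adjusted p = 0.00279), Pfkp 2.31-fold, Aldoc 3.98-fold and Pgam1 1.80-fold. The list had a median of 0.28 (camera adjusted p = 0.0055; adjusted p = 0.810 with an estimated correlation). The count of 7 was 1 without GFP replicate 1 or 2, 3 without GFP replicate 3 or G392E-NS replicate 2, and 4 without G392E-NS replicate 3, and the median was 0.13 without G392E-NS replicate 2 and 0.15 with length and GC trends removed. Aldoc is also an astrocyte marker, and astrocyte markers had a median of 1.24 in these libraries.

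All 21 cholesterol synthesis genes tested had a fold change above 0, though none passed over all genes or adjusted over the list alone (edgeR quasi-likelihood test). DESeq2 called 3 of them and 3 were called with no low-count filter. The nearest was Mvd, with a log2 fold change of 0.92 (SE 0.23, adjusted p = 0.0566). Their median was 0.42 (camera adjusted p = 0.00824; adjusted p = 0.854 with an estimated correlation), a call lost without GFP replicate 2 (0.164, median 0.19) and without G392E-NS replicate 2 (0.145, median 0.21). Of 22 p53 target and apoptosis genes none passed (0 adjusted over the list alone, 3 higher and 1 lower by DESeq2), the nearest being the stress-induced Sesn1 (0.52, SE 0.14, adjusted p = 0.0706), and the list did not shift (median 0.08, adjusted p = 0.564). Of 41 ribosomal protein genes 1 fell, Rpl24, by 0.67 (adjusted p = 0.0418; 0 adjusted over the list alone), and the list median was −0.09 (adjusted p = 0.0542). It passed without GFP replicate 1 (0.00506) and without G392E-NS replicate 3 (5.48e-07, median −0.25), while its median was 0.00604 without G392E-NS replicate 2. Without GFP replicate 1 or GFP replicate 2, Uqcrfs1, Cox5a, Ndufs1, Cox6a1, Pfkp, Aldoc, Pgam1 and Rpl24 lost their calls (0.0636 to 0.172 and 0.055 to 0.154). Without GFP replicate 3 all of these but Pfkp and Aldoc did (0.0641 to 0.108), as did Ndufs1, Pgam1 and Rpl24 without G392E-NS replicate 2 (0.0523 to 0.0724) and Ndufs1 and Rpl24 without G392E-NS replicate 3 (0.0561 and 0.084). Mvd and Sesn1 passed without G392E-NS replicate 1 (0.0266 and 0.0098), where 2 p53 targets were higher and 1 lower. Without G392E-NS replicate 3, 2 ribosomal protein genes were lower.

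Astrocyte markers rose most clearly of the cell type lists. Of 24 tested, 13 rose and none fell (19 adjusted over the list alone), with a median log2 fold change of 1.24. The adhesion gene Hepacam (ENSMUSG00000046240, chromosome 9, 37367351 to 37386575) rose 7.20-fold from 29.9 ± 4.63 to 216 ± 38.1 CPM (SE of the log2 fold change 0.17, adjusted p = 0.000153). The growth factor receptor gene Fgfr3 rose 2.96-fold, the apolipoprotein gene Clu 7.75-fold and the gap junction gene Gjb6 12.8-fold. Gfap, the intermediate filament of astrocytes, had 0.365 ± 0.298 CPM in GFP and 10.4 ± 13.6 CPM in G392E-NS libraries, with 26.2 CPM in G392E-NS replicate 2. Its log2 fold change of 4.79 (SE 1.16) did not pass (adjusted p = 0.0511), though it passed without G392E-NS replicate 1 (0.0347), replicate 2 (0.0473) or replicate 3 (0.0459). Camera placed the list above other genes (adjusted p = 1.31e-20; adjusted p = 0.810 with an estimated correlation). The count of risen members was 7 without GFP replicate 1 and 5 without GFP replicate 2, against 13, while Hepacam, Fgfr3, Clu and Gjb6 kept their calls. In the same libraries Xist was higher and the Y-linked genes were lower.

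Of 15 oligodendrocyte lineage markers, 3 rose and 1 fell (3 and 1 adjusted over the list alone). Mog, Nkx2-2 and Pdgfra, a receptor of oligodendrocyte precursors, rose by 2.25, 3.96 and 1.12 and Bcas1 fell by 0.47. Mog and Nkx2-2 were low, at 1.02 ± 0.41 and 1.61 ± 1.14 CPM in G392E-NS libraries. With at least 1 CPM required in 3 libraries, 1 marker rose and 1 fell. The list median was 0.12 (adjusted p = 0.272, and 0.0419 without GFP replicate 3). Mog, Nkx2-2, Pdgfra and Bcas1 lost their calls without GFP replicate 1 (0.0757 to 0.172), GFP replicate 2 (0.0795 to 0.155) or GFP replicate 3 (0.0512 to 0.0852). Without G392E-NS replicate 2, Mog, Bcas1 and Pdgfra did (0.0538 to 0.0798), and Bcas1 without G392E-NS replicate 1 (0.0501). Microglia and macrophage markers were represented by 2 genes with enough counts, so no list test was run (0 rose or fell, median 0.32). Of 6 endothelial and mural markers none passed (0 adjusted over the list alone, median 0.14, adjusted p = 0.663), the nearest being Acta2 (1.47, adjusted p = 0.203).

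Neuron markers moved both ways. Of 28 tested, 1 rose and 2 fell (5 and 2 adjusted over the list alone): the growth cone gene Gap43 rose by 1.11 (SE 0.15, adjusted p = 0.00585), while Neurod1 and the RNA-binding protein gene Elavl4 fell by 2.63 and 0.70. The tubulin gene Tubb3 had a log2 fold change of 0.33 (adjusted p = 0.364) and passed without GFP replicate 3 (0.0369), where 3 neuron markers were called higher. The dendritic protein gene Map2 had −0.06 (SE 0.15, adjusted p = 0.843), which became 0.01 without G392E-NS replicate 3. The list did not shift (median 0.15, adjusted p = 0.499). Of 22 glutamatergic synapse genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone), and the lower count was 0 without GFP replicate 1, 2 or 3 or G392E-NS replicate 2 or 3 and 2 without G392E-NS replicate 1. The AMPA receptor gene Gria4, named after its value was seen, fell by 0.58 (SE 0.12, adjusted p = 0.0291). The AMPA receptor gene Gria1 rose 22.8-fold from 0.0694 ± 0.0398 to 1.65 ± 0.0989 CPM, the kainate receptor gene Grik2 2.52-fold from 38.2 ± 7.22 to 96.5 ± 11.5 CPM and the scaffold gene Shank2 2.54-fold. The list median was 0.09 (adjusted p = 0.0593, and 0.043 without GFP replicate 1 and 0.00326 without G392E-NS replicate 2), and it turned to −0.09 without G392E-NS replicate 1. Of 11 GABAergic genes 1 rose and 2 fell (3 and 3 adjusted over the list alone): the receptor gene Gabra3 rose by 2.92, and Gad1, which makes GABA, and Reln fell by 0.65 and 1.64. That list had a median of 0.09, a mean of 0.15 and a downward camera direction (adjusted p = 0.663). Elavl4, Shank2, Gad1, Reln and Gabra3 lost their calls without GFP replicate 1 (0.0539 to 0.127) or GFP replicate 2 (0.0513 to 0.106), Elavl4 also without GFP replicate 3 (0.0657) and G392E-NS replicate 2 (0.0674), Gabra3 without G392E-NS replicate 1 (0.0502), and both without G392E-NS replicate 3 (0.051 and 0.0525).

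Of 25 progenitor and radial glia markers, 3 rose and 1 fell (3 and 4 adjusted over the list alone). Prom1 rose by 2.52 (SE 0.29, adjusted p = 0.00303), the cortical transcription factor gene Lhx2 by 0.56, and the intermediate filament gene Nes fell by 0.77 (SE 0.18, adjusted p = 0.048). The list did not shift (median 0.02, adjusted p = 0.974). Of 28 cell cycle genes none passed over all genes or adjusted over the list alone by edgeR, and DESeq2 called none; the nearest was Tyms (−0.47, SE 0.15, adjusted p = 0.108). Only 3 of the 28 had a fold change above 0, the median was −0.48, and camera placed the list below other genes (adjusted p = 0.0423; adjusted p = 0.854 with an estimated correlation). That call was lost without GFP replicate 1 (0.077), GFP replicate 2 (0.337), G392E-NS replicate 1 (0.173) or G392E-NS replicate 2 (0.0805), with library totals alone (0.0776), with at least 1 CPM in 3 libraries (0.0582) and with length and GC trends removed (0.109). Without GFP replicate 3, 4 cell cycle genes were called lower and the list median was −0.86, and without GFP replicate 2 it was −0.17. Lower progenitor markers numbered 2 without GFP replicate 3 or G392E-NS replicate 2 and 3 without G392E-NS replicate 1.

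Matrix genes held some of the larger changes. Of 26 extracellular matrix and adhesion genes, 2 rose and 1 fell (7 and 3 adjusted over the list alone). The proteoglycan gene Vcan (ENSMUSG00000021614, chromosome 13, 89655312 to 89742509) rose 25.6-fold from 2.92 ± 0.499 to 74.4 ± 37.9 CPM (adjusted p = 0.000729), the protease inhibitor gene Timp3 4.98-fold (adjusted p = 0.000797), and Col5a2 fell 9.49-fold. Timp3 lies within Syn3, so its count may hold reads of that gene. These genes had a median of −0.10 and a mean of 0.19 with an upward camera direction (adjusted p = 0.326). Without G392E-NS replicate 1, 5 of them were called higher, with 6 by DESeq2 and 7 with no low-count filter. Of 6 fibroblast and meningeal markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone): Thy1, which neurons also express, rose by 4.24 (SE 0.38, adjusted p = 0.000896) and Fbln1 fell by 1.30 (list median 0.12, adjusted p = 0.499). Of 6 serpins and plasminogen system genes none passed over all genes (1 adjusted over the list alone), the nearest being Serpinb9 (1.59, SE 0.44, adjusted p = 0.0745, and 0.037 without G392E-NS replicate 1), and the list did not shift (median 0.21, adjusted p = 0.421). Nes, Lhx2 and Fbln1 lost their calls without GFP replicate 1 (0.0916 to 0.170), GFP replicate 2 (0.0526 to 0.163) or GFP replicate 3 (0.0657 to 0.0893). Fbln1 also did without G392E-NS replicate 1 (0.0631), Nes and Fbln1 without G392E-NS replicate 2 (0.0754 and 0.0972), and Nes without G392E-NS replicate 3 (0.104).

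**Figure D3:**
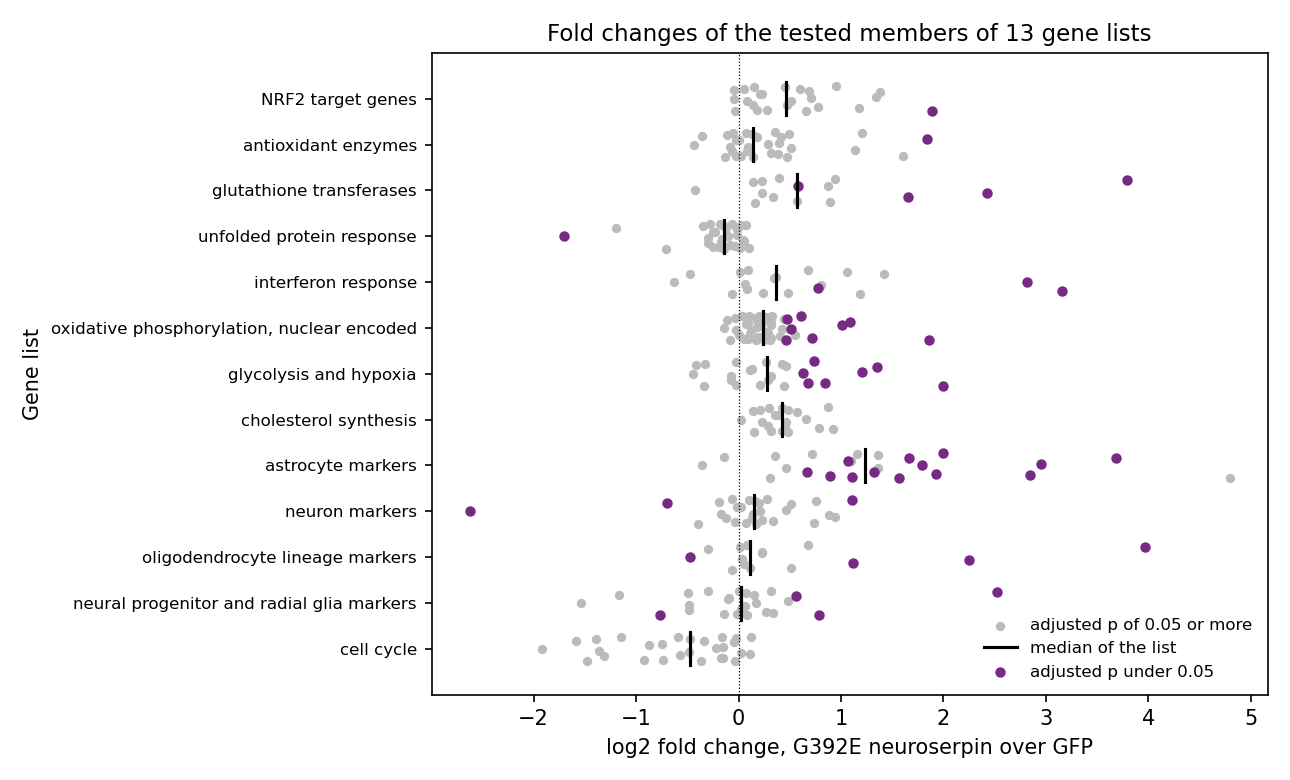
Log2 fold changes of G392E neuroserpin over GFP for the tested members of 13 gene lists, with 1 point per gene (purple for an adjusted p under 0.05, grey otherwise, spread vertically for visibility) and a black bar at each list's median. Astrocyte markers have the highest median of the lists drawn, 1.24, and cell cycle genes the lowest, −0.48.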

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

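The alternatives without X and Y genes and with length and GC trends removed were chosen after seeing the data. Against 660 higher and 187 lower genes, DESeq2 called 1098 and 352 and the fit with no low-count filter 1205 and 374. With the replicate number as a block there were 217 and 50. The numbers are not a pairing in the labels, and same-number libraries had deviation correlations of 0.0338, −0.383 and −0.255. With length and GC trends removed 442 were lower, and 86 lower genes were at least 2-fold. Leaving out 1 library at a time gave 196 to 981 higher and 46 to 3.9e+02 lower genes (the latter to 2 digits), and 6 to 11 shifted lists against 9. With 5 libraries fewer samples carry each test. The lists numbered 0 with an estimated correlation and 0 by fry for direction, against 20 by fry's mixed test. Other totals of genes and of lists stayed within 1.5 times, while counts of called members within single lists moved further and list medians near 0 changed sign in some settings. With X and Y genes left out 766 calls remained. The block left 5 astrocyte markers called against 13 and ended the call of the cell cycle list (camera adjusted p = 0.0749). Map2, uncalled throughout, ranged from −0.21 without G392E-NS replicate 1 to 0.0139 without G392E-NS replicate 3. Of 93 genes picked by the rule for named genes, 75 were called and none of these reversed. Calls of 31 held in all settings, and 6 of 18 uncalled genes passed in some setting. The cause was not tested for any of these shifts. Depth limits genes near 1 CPM, where 15507487 counts, the smallest library, give few reads per gene.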

Other observations

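The regional gene lists, the sex-linked genes and the on and off genes below were chosen after results had been seen, as were the tests for Xist in XY cells, loss of Y, dosage of X and Y, length and GC trends, another cell type and a single library. Genes of forebrain identity were higher in G392E-NS libraries. Of 12 tested, 6 rose and none fell. Setting aside those already seen, 4 of 8 rose: Otx1 by 1.24 (adjusted p = 0.00503), Nr2f1 by 0.67 (adjusted p = 0.013), Dmrta2 by 1.79 (adjusted p = 0.00738) and Dmrt3 by 3.24 (adjusted p = 0.00841). These 8 had a median log2 fold change of 0.96, with an unadjusted camera p of 4.16e-06 and p = 0.00888 with an estimated correlation. Of 14 midbrain and hindbrain genes 5 fell, with log2 fold changes of −3.37 for En2, −3.13 for Cnpy1, −1.67 for Zic1, −2.36 for Zic4 and −1.36 for Gbx2. All of these but Gbx2 had been seen before the list was drawn up, and among the 10 not seen before 1 fell. Zic1 and Zic4 overlap, so reads of the pair may be shared.

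Several genes were near 0 in the GFP group and present in the G392E-NS group. With at most 3 counts over GFP and at least 1 CPM in G392E-NS, 16 genes were found, among them Scarf2 (2 against 181 counts), Matn4 (3 against 129) and Luzp2 (2 against 124). The reverse held for 1 gene, Ms4a6b, with 93 counts in GFP and 0 in G392E-NS libraries. Called genes also lay side by side. The S100 genes S100a1 and S100a13 rose by 5.89 and 6.03, the cell cycle inhibitor genes Cdkn2a and Cdkn2b by 4.59 and 3.66, and Scara3, Clu and Ephx2 by 3.66, 2.95 and 3.99. Ifitm2 and Ifitm3 rose by 1.98 and 4.92. Protocadherin genes Pcdhb17 to Pcdhb21 on chromosome 18 fell by 0.52 to 0.74, and are similar in sequence.

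Over 13119 autosomal genes, 75 adjacent pairs were called in the same direction, of which 65 do not overlap. Shuffled positions gave a median of 32 and at most 53 in 10000 shuffles (permutation p = 1e-04, the smallest possible). Neighbouring genes of 1 family or function are themselves co-regulated, so this value does not separate regional differences between cultures from shared regulation. No biological explanation was tested for it.

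Xist was higher and the Y-linked genes were lower in each G392E-NS library than in any GFP library. Were Xist switched on in XY cells, Y-linked genes would keep their level, but their median was −0.95, which argues against that. Were Y lost from part of the cells, Xist would stay low, but it rose by 9.95, which argues against that as a whole. A mix of XX and XY cells remains open. It predicted that the 4 X genes that escape inactivation would have a median above 0, with at least 3 of 4 above 0. That was met, with a median of 0.12 and 3 of 4 above 0. None of the 4 passed the gene test, and the requirement that at least 1 pass was added after these values were seen. Sex composition may therefore differ with the variant, and the labels do not give the sex of the embryos.

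The genes differing between the groups could in part follow from how the cultures arose, since the variant and the culture cannot be separated here. X and Y hold 5.79% of the calls, so that the dosage of their own genes cannot make up most of them, while effects of that dosage on autosomal genes were not tested. Of 494 X genes tested 30 rose and 15 fell, and of 5 Y genes 4 fell, where 6.15% of all genes tested were called. Trends of gene length and GC content likewise leave 787 of the calls with the same sign. For cultures from a different origin along the brain, the 10 midbrain and hindbrain genes not seen before had a median of −0.0900 with 6 of 10 below 0 and an unadjusted camera p of 0.186 (0.239 with an estimated correlation), so that the shift foreseen for them was not found, while the 8 forebrain genes not seen before had a median of 0.96, which leaves it open. Of the 10 ways to split the libraries into 3 and 3, 1 of 10 gave as many as 660 genes in a direction and 1 of 10 as many as 187, the real one each time, with 0 as the highest of the others, while 5 of 10 gave as many as 9 lists, with 16 as the highest of the others; a share under 0.1 cannot arise.

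The higher astrocyte markers suggest more astrocyte-like cells or expression, which is set here against technical sources. A lower share of a single other cell type would raise the markers of all remaining types alike. The astrocyte median exceeded the neuron median by 1.09 (permutation p = 1e-05, the smallest possible) and the oligodendrocyte median by 1.12 (permutation p = 0.00077). Fewer neurons would themselves open the gap to neuron markers, so for neurons only the oligodendrocyte gap counts against it. The permutation draws genes as if independent, while the astrocyte list had an estimated correlation of 0.46. Its p-values may therefore overstate the evidence, and a lower share of another cell type remains open. G392E-NS replicate 2 as the sole source is argued against, since without it the median was 0.97 and 12 members were called. Leaving out each library in turn gave medians of 0.97 to 1.37, though 5 members were called without GFP replicate 2. With length and GC trends removed 14 were called, and whether the variant or the culture raised them was not tested.

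Within groups, libraries higher in astrocyte markers were higher in the 69 genes of the NRF2, antioxidant and glutathione transferase lists, with a Pearson correlation of 0.85 over 6 libraries (exact permutation p = 0.0278, the smallest of 36, and adjusted p = 0.429 over 27 relations). The rank correlation was 0.83 (exact permutation p = 0.0278), and without G392E-NS replicates 1 and 2 the Pearson correlation was 0.71. A comparison with 26 other lists, added after the value was seen, gave 1 as high, ER-associated degradation at 0.90, and a median of 0.36. The oxidative stress genes may thus move with astrocyte content, and these data cannot assign them to the neuroserpin variant.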
